A study of Mus musculus with 461 samples.

How the data were processed

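The values came from 461 single mouse cells, each of which is 1 sample of the series. Reads were demultiplexed with bcl2fastq and quantified with RSEM 1.2.22, per the submitters' processing notes. The aligner, the genome build and the annotation release are not given in the sources used here, so genes are named by symbol and Ensembl identifier without coordinates. The deposited expected counts are RSEM estimates of reads per gene and cell, and 9.108% of the values are not whole numbers. The deposited TPM values (relative transcript abundance) were scaled within each cell by the authors, and their sums per cell ran from 994110 to 999272. No cell was removed, and no count of the tables was corrected. The count table held 31673 genes, of which 31426 identifiers had a symbol in the reference. Of the genes in the TPM table, 31138 matched by name, 471 of them through an older symbol. Genes of the mitochondrial genome were not analysed here, which leaves 27 of the 28 gene lists.

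Cells are not replicates. A replicate was the set of all cells that share a title prefix (b1, b2 or b3) and a day, and the labels do not say what the prefix stands for. P-values therefore measure the spread between sets, shared over genes, and say nothing about animals or repeated derivations. Expected counts were summed over the cells of each set and rounded after summing. The 8 sets with 10 or more cells entered 1 fit in edgeR, with TMM factors from 0.8332 to 1.146, filterByExpr by day, a quasi-likelihood fit on day and no block on the prefix. Only days 0 and 3 had 2 sets, which left 2 residual degrees of freedom, and edgeR estimated infinite prior degrees of freedom. The p of a gene therefore rests on the spread shared over genes and not on that gene's own spread between sets. A gene that differed widely between 2 sets of a day can thus still have a small p. Days 1, 4, 5 and 7 had 1 set each and were assumed to vary as days 0 and 3 did. Day 4 was the only day of prefix b3, so that day and that prefix cannot be told apart. Pairing by prefix was not used.

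The test was the edgeR quasi-likelihood F test, two-sided, on 22378 genes. A gene changed when its Benjamini-Hochberg adjusted p was under 0.05. CPM are counts scaled per mega-count with TMM factors, given as mean ± SD where a day had 2 sets. Fold changes are log2 values with a standard error computed as the absolute log2 fold change over the square root of F. Where 1 day of a comparison had 0 counts, "at least N-fold" takes 3 counts for that day. Where it had 1 to 3 counts, the ratio carries an exact binomial 95% interval. Shares of cells used a TPM of 1 or more as detection and exact Clopper-Pearson 95% intervals. A limit printed for a gene found in no cell of a set is 3 over the number of cells. Intervals and limits cover counting error only, because C1 reads carry no molecular identifiers.

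Gene lists were tested with limma camera at a preset correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over the 27 lists of a comparison. No list call of any comparison held with an estimated correlation, and the range of its p is given for the lists of each comparison. A bounded median replaces each fold change of a gene without counts by its bound. Scores per cell are means of log2(TPM + 1) over a list. For thinned counts, each cell was brought to 300000 counts by random draws. Clusters came from scanpy with 2000 variable genes, 20 components, 15 neighbours and Leiden clustering at resolution 0.5. No doublet caller was run.

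Sets, tests, gene lists, cell marker lists and the rule for naming genes were chosen before the data were examined. For each comparison the rule names the 8 largest rises and the 8 largest falls among genes with adjusted p under 0.05, at least 50 CPM in every set of the higher day and no overlap between the sets of both days. Predicted genes, pseudogenes, ribosomal proteins and histones are excluded from that part. The rule adds up to 4 members of each list that passed and up to 2 that did not, some of which are left out for length. Some genes that the rule names are not reported here. It always adds the 7F factors, Pou5f1, Sox2, Zfp42, Dppa5a, Cdh1, Epcam, Thy1, Col1a1, Twist1, Cdkn1a, Cdkn2a and Mki67.

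A self-test multiplied 200 of 21586 genes by known factors in 5 draws. For day 3 against day 0 the test recovered 2.4% of changes of 2-fold, 34% of 4-fold, 70% of 8-fold and 85.2% of 16-fold. For day 7 against day 0 it recovered 0.4%, 14.8%, 53.2% and 67.6%. False calls averaged 2.6 and 3 genes per draw. A gene without a call can therefore have changed by 2-fold or 4-fold, and at day 7 even by 16-fold. For day 1 against day 0 no gene was changed, so recovery there was not measured. The software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, leidenalg 0.10.2 and matplotlib 3.10.9.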

Results

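Single-cell RNA sequencing on the Fluidigm C1 system measured transcripts in 461 mouse cells taken on 6 days of a reprogramming course named 7F in the titles. The starting cells were OG2 mouse embryonic fibroblasts, which carry a green fluorescent reporter of Oct4 (Pou5f1), kept in medium with 10% serum. During reprogramming the cells grew in iCD1, a chemically defined medium. The labels do not name the 7 factors. The published 7F cocktail consists of Jdp2, Kdm2b (Jhdm1b), Map2k6 (Mkk6), Glis1, Nanog, Esrrb and Sall4, and vector and native transcripts of these genes cannot be told apart in gene counts. The title prefixes b1, b2 and b3 divide the cells of a day into sets. Day 0 held 74 cells, 20 of prefix b1 and 54 of b2. Day 1 held 58 cells of b2, and day 3 held 61 of b1 and 58 of b2. All 59 cells of day 4 were of b3. Day 5 held 79 cells of b2 and 5 of b1, and day 7 held 65 of b2 and 2 of b1. Counts per cell ran from 0.319 to 6.999 M (M, mega) with a median of 2.503 M, and 6270 to 12141 genes per cell had counts. The median count per cell was 2.87 M in b1 and 3.31 M in b2 at day 0, 2.54 M at day 1, 3.10 M in b1 and 1.9633 M in b2 at day 3, 0.983 M at day 4, 2.30 M in b2 at day 5 and 3.18 M in b2 at day 7. The summed counts of the 8 sets with 10 or more cells ran from 58.394 M (day 4) to 208.883 M (day 7). Days 0 and 3 had n = 2 sets and the other days n = 1, so values of days 1, 4, 5 and 7 carry no SD.

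The factor transcripts were abundant at day 0, before the course began by its label. Sall4 (ENSMUSG00000027547) was at 669 ± 60.1 CPM, Esrrb (ENSMUSG00000021255) at 1129 ± 247, Nanog (ENSMUSG00000012396) at 574 ± 142, Map2k6 (ENSMUSG00000020623) at 582 ± 129, Jdp2 (ENSMUSG00000034271) at 376 ± 42.8 and Kdm2b (ENSMUSG00000029475) at 339 ± 9.41, while Glis1 (ENSMUSG00000034762) was at 6.301 ± 3.129. Of the native pluripotency genes Dppa5a (ENSMUSG00000060461) was at 0.0033 CPM on the same day and Zfp42 (ENSMUSG00000051176) had no count, while Klf4 (47.9 CPM) and Tbx3 (41.9 CPM) were expressed. The plot of factor CPM by day shows that no factor fell detectably up to day 3, that Map2k6 was low in the day 4 set, and that 5 factors were lower at day 5 than at day 0.

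**Figure D1:**
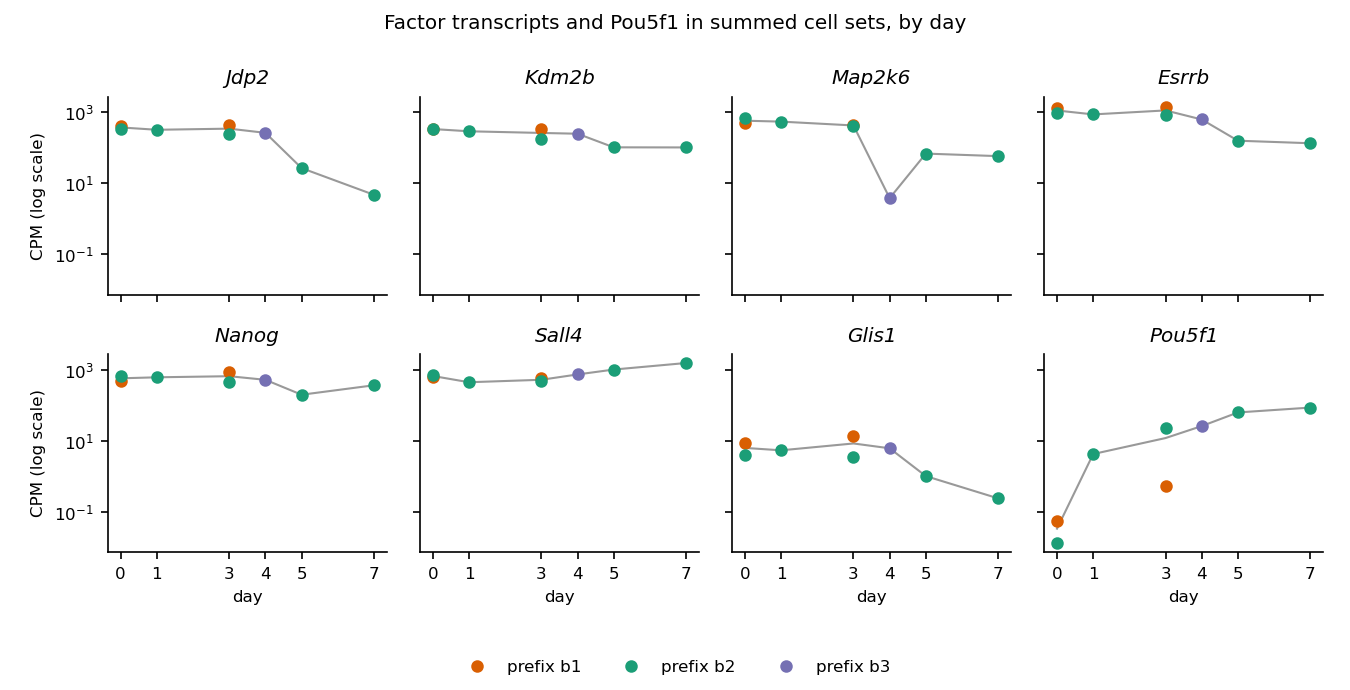
CPM of the 7F factors and Pou5f1 (log axis) against day, with 1 point for each set of 10 or more cells and lines through the day means. Map2k6 was at 3.84 CPM in the day 4 set, and Jdp2 was at 26.9 CPM at day 5 and 4.76 CPM at day 7.

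The comparison of day 1 with day 0 set the day 1 cells, all of prefix b2, against both day 0 sets. After 1 day 7 of 16 contractile and 4 of 30 fibroblast and mesenchyme genes were lower, and 6 of 25 pluripotency genes were higher. Tdh (ENSMUSG00000021953), the threonine dehydrogenase that mouse embryonic stem cells depend on, rose by a log2 fold change of 12.01 ± 0.72 (SE; adjusted p = 1.22e-58), from 0.0269 ± 0.0381 CPM to 70.9 CPM, a ratio of 4885 (1671 to 23690) over the 3 counts of day 0. Sox2 (ENSMUSG00000074637) rose by 6.59 ± 0.89 (adjusted p = 2.68e-10), from 0.288 ± 0.154 to 28.6 CPM, and had counts in 56 of 58 cells. Pou5f1 (ENSMUSG00000024406) rose by 7.21 ± 1.05 (adjusted p = 9.57e-09) to 4.23 CPM in 14 of 58 cells. Of 25 pluripotency genes 6 rose, or 9 with 2 lower when adjusted over the list alone, among them Nr0b1 (at least 253.6-fold), Utf1 (ratio 254.1, 44.91 to 10100) and Dppa5a (ratio 32.63, 5.186 to 1356, no call in DESeq2). The list median was 0 (camera adjusted p = 0.199). The other largest rises were the neurofilament gene Nefm (4.84), the receptor gene Tnfrsf19 (4.80), the insulin gene Ins2 (4.63, no call in DESeq2), the transporter gene Slc16a6 (4.34), and Ptgds (5.56), Penk (5.15) and Gal (4.93), of which 1 cell held 69.8%, 77.4% and 81.6% of the day 1 counts. DESeq2 did not call Ptgds or Penk. Without each gene's highest cell in each set Ptgds (0.302), Gal (0.303) and Dppa5a (0.298) were not called.

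Of 16 contractile and TGF-beta response genes 7 fell at day 1, 12 when adjusted over the list alone, with a median of −2.53 (camera adjusted p = 1.97e-06). The members included Ankrd1, a target of YAP (−6.06 ± 0.74), the calponin gene Cnn1 (−3.95 ± 0.78), Ccn2 (−3.78 ± 0.74, 66% of the day 0 counts in 1 cell) and the smooth muscle gene Tagln (−2.71 ± 0.51, 417 against 2733 ± 2243 CPM). Of 30 fibroblast and mesenchyme genes 4 fell, 11 when adjusted over the list alone (median −0.88, camera adjusted p = 5.96e-05). They were the collagen crosslinker gene Lox (−3.56, adjusted p = 0.0847 without the highest cell of each set), Thbs1 (−3.40), Col1a2 (−2.08) and Col1a1 (ENSMUSG00000001506), at −2.07 ± 0.51 (adjusted p = 0.00806). The other largest falls were the chemokine genes Ccl2 (−4.98) and Cxcl12 (−3.53), Crispld2 (−4.92, 0.128 without the highest cell of each set), the tissue factor gene F3 (−3.93) and the Wnt inhibitor gene Sfrp1 (−3.75, or −4.37 without cells with few genes). G2/M genes had a median of −0.53 with no member called (camera adjusted p = 0.000388). Per cell, the median G2/M score of b2 went the other way, from 1.3572 at day 0 to 2.051 at day 1. That of b1 at day 0 was higher than both. Interferon response genes had a median of −2.11 with 1 call, Cxcl10, or 6 over the list alone (camera adjusted p = 0.00947). The median interferon score per cell of b2 did not fall, with 0.4866 at day 0 and 0.5874 at day 1. Cholesterol synthesis genes had a median of 0.61 with 1 rise, Insig1 (1.69 ± 0.48), or 2 over the list alone (camera adjusted p = 0.00947). With an estimated correlation the adjusted p of these 5 lists was 0.757 to 0.805. Of the imprinted genes Peg3 (−2.71), Rian (−2.64) and Meg3 (−2.62) fell. All 7 factors differed from day 0 by −0.59 to 0.09 without a call (each adjusted p = 1), and neither Zfp42 (5 counts, adjusted p = 0.101) nor Epcam (2.38), Cdh1 (−0.52), Thy1 (−1.67), Twist1 (0.36), Cdkn1a (0.90), Cdkn2a (−0.95) or Mki67 (−0.92) was called.

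At day 1 limma on TPM called 0 genes (1316 of 17892 with an unadjusted p under 0.05, against 1595 of 22378 in edgeR). In total 265 of 22378 genes changed in edgeR, 209 (78.9%) higher and 56 lower, against 723 with DESeq2 (53.9% higher) and 1 with all 10 sums. Without the b2 set of day 0 the count was 440 and Ccl2 (−2.04, adjusted p = 0.166), Cnn1 (−2.81, 0.184) and F3 (−2.34, 0.0583) lost their calls. Without the b1 or the b2 set of day 3 it was 145 or 150, and Col1a1 (0.101 and 0.109) lost its call, as did Crispld2 (0.0977, without b2 of day 3) and Cxcl12 (0.086, without b1 of day 0), while Epcam gained one without b1 of day 0 (8.94, 0.000481), and leaving out 1 set at a time gave log2 ranges of Ccl2 −5.89 to −2.04, Cnn1 −4.57 to −2.81, Cxcl12 −4.02 to −2.80, Dppa5a 4.42 to 7.48, F3 −4.67 to −2.34, Ins2 3.63 to 14.30, Nefm 4.19 to 6.01, Penk 4.17 to 17.05, Pou5f1 6.27 to 8.24, Ptgds 4.57 to 16.41, Sfrp1 −4.39 to −2.58, Slc16a6 3.89 to 5.03, Sox2 6.17 to 7.31 and Tdh 10.34 to 16.41.

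At day 3, compared with day 0, 12 of 16 contractile genes were lower and 18 of 25 pluripotency genes were higher. Acta2 (ENSMUSG00000035783), the smooth muscle actin of activated fibroblasts, fell by 8.62 ± 0.51 (adjusted p = 5e-59), from 1786 ± 840 to 4.52 ± 1.99 CPM. Of the 16 contractile and TGF-beta response genes 12 fell, 13 over the list alone (median −3.28, camera adjusted p = 1.91e-10). They included Ankrd1 (−9.85 ± 0.63), Cnn1 (−7.25 ± 0.68), Tagln (−6.34 ± 0.46) and Myl9 (−4.89 ± 0.56). Of 30 fibroblast and mesenchyme genes 10 fell, and over the list alone 13 fell and 1 rose (median −1.17, camera adjusted p = 1.91e-10). Lox fell by 7.47 ± 0.66, Thbs1 by 4.44 and Col1a1 by 3.73 ± 0.42, to 89.6 ± 25.03 CPM. Inhba, which encodes an activin subunit, fell by 5.27 and the intermediate filament gene Des by 4.66. Of 25 pluripotency genes 18 rose, also over the list alone, with a median of 8.34, or 5.76 with bounds (camera adjusted p = 8.83e-07). Tdh rose by 13.27 ± 0.72, to 169 ± 106 CPM, a ratio of 10430 (3570 to 50600). Dppa5a reached 20.6 ± 28.2 CPM, a ratio of 3285 (589.3 to 129800), and Zfp42 reached 9.32 ± 13.1 CPM, at least 492-fold. Pou5f1 rose by 8.70 ± 1.05 (adjusted p = 1.37e-13) to 11.95 ± 16.16 CPM and Sox2 by 7.00 ± 0.87 to 37.9 ± 26.3 CPM. Nr0b1 rose at least 938-fold and the epithelial adhesion gene Epcam by 7.14 ± 1.06 (no call in DESeq2). Dppa5a was detected in 6.56% of the b1 and 41.4% of the b2 cells of day 3.

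The other largest rises at day 3 were Nefm (5.17, 66% in 1 cell), the selenium transport gene Selenop (4.56 ± 0.45, 481 ± 37.2 against 20.4 ± 3.56 CPM), the pyruvate dehydrogenase kinase gene Pdk1 (4.04 ± 0.47, 303 ± 15.3 against 18.4 ± 18.1 CPM), Tnfsf9 (3.85), Chchd10 (3.71), Crym (3.70) and Cyyr1 (3.57). BMP response genes had a median of −0.86 with 1 fall, Id3 (−1.53 ± 0.37), or 2 over the list alone (camera adjusted p = 0.00273). Imprinted genes had a median of −0.66 (camera adjusted p = 0.00819), with Rian, Peg3 and Meg3 lower and Plagl1 higher. Endothelial genes had a median of 3.05 with 2 rises, or 6 over the list alone (camera adjusted p = 0.021), and both called members, Tek (at least 87.44-fold) and Emcn (at least 53.39-fold), were low in counts, those of Emcn all in 1 cell. With an estimated correlation the adjusted p of these 6 lists was 0.693 to 0.771. The 7 factors differed from day 0 by −0.45 to 0.42 without a call, and so did Cdh1 (0.21), Thy1 (0.17), Twist1 (−0.01), Cdkn1a (0.37), Cdkn2a (0.27) and Mki67 (−0.04).

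At day 3 limma on TPM called 0 genes (2051 of 17892 with an unadjusted p under 0.05, against 2591 of 22378 in edgeR). In total 703 genes changed in edgeR, 470 higher and 233 lower, against 1549 with DESeq2 and 37 with all 10 sums. The count was 338 without the b1 and 261 without the b2 set of day 3, and without the latter Dppa5a stood at 6.90, Zfp42 at 6.77, Pou5f1 at 4.19 and Epcam at 3.38 (adjusted p = 0.166), and leaving out 1 set at a time gave log2 ranges of Cnn1 −7.88 to −6.12, Crym 3.18 to 4.52, Cyyr1 3.00 to 4.54, Des −6.76 to −3.84, Dppa5a 6.90 to 14.49, Epcam 3.38 to 13.70, Inhba −6.25 to −4.69, Lox −8.24 to −6.97, Myl9 −6.68 to −4.12, Nefm 4.52 to 6.35, Pdk1 3.28 to 5.76, Pou5f1 4.19 to 9.73, Sox2 6.03 to 7.71, Tagln −7.40 to −5.09, Tdh 11.59 to 17.67, Tnfsf9 2.92 to 7.53 and Zfp42 6.77 to 14.25.

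The day 4 set, the only one of prefix b3, had more pluripotency transcripts and far fewer Map2k6 transcripts than day 0. Map2k6, a kinase upstream of p38, was at 3.84 CPM against 582 ± 129 (−7.24 ± 0.69, adjusted p = 3.51e-22), and at 0.898% of its day 3 mean. The other 6 factors were at 55.5% (Esrrb) to 141% (Sall4) of their day 3 means and differed from day 0 by −0.84 to 0.14 without a call. The factor list had a median of −0.44 (camera adjusted p = 0.0436). Of 25 pluripotency genes 20 rose, also over the list alone (median 10.12, bounded 7.99, camera adjusted p = 2.02e-09). Lin28a rose at least 4279-fold, Zfp42 at least 1783-fold, Dppa3 (ENSMUSG00000046323) at least 1735-fold and Dppa4 at least 930.3-fold. Dppa5a reached 67.4 CPM, a ratio of 13950 (2502 to 550900), Tdh 229 CPM, a ratio of 15780 (5398 to 76520), Pou5f1 25.99 CPM (9.82 ± 1.12) and Sox2 37.9 CPM (7.00 ± 0.90). The other largest rises were the mesoderm gene T (at least 4394-fold, 55% in 1 cell), Rnase10 (at least 3933-fold, 71% in 1 cell), the thyrotropin-releasing hormone gene Trh (ratio 28950, 8014 to 239100, 56% in 1 cell), Penk (6.07, 70% in 1 cell) and the retinol uptake gene Stra6 (5.88 ± 0.81). DESeq2 did not call T, Penk or Epcam.

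Of 16 contractile and TGF-beta response genes 11 fell, 12 over the list alone (median −4.08, camera adjusted p = 3.96e-08), among them Cnn1 (−6.68), Tagln (−6.20 ± 0.62) and Acta2 (−5.80 ± 0.62). Of 30 fibroblast genes 11 fell, 14 over the list alone (median −1.54, camera adjusted p = 2.42e-08), with Lox at −6.18, the periostin gene Postn at −4.23 and Col1a1 at −3.92 ± 0.57. F3 (−5.96) and the cytokine gene Clcf1 (−5.57) were also among the largest falls. Of 25 epithelial genes 4 rose and 1 fell, or 9 and 1 over the list alone (median 1.46, bounded 1.10, camera adjusted p = 0.0136). Epcam rose by 6.88 ± 1.09, Ap1m2 at least 513.1-fold and the transcription factor gene Elf3 at least 311.1-fold. Cdh1 (ENSMUSG00000000303), which encodes E-cadherin, stood at 1.62 (adjusted p = 0.11), but was called without the b1 set of day 0 (2.27, 0.00679) and without the highest cell of each set (3.37, 0.000464). BMP response genes had a median of −1.82 (2 fell, 4 over the list alone, camera adjusted p = 8.54e-05), with Smad7 at −2.78 and Id3 at −2.65. Endothelial genes had a median of 3.88 (camera adjusted p = 0.000359) and germline genes 4.16, bounded 1.05, with no member called (0.0102). Medians were also below 0 for AP-1 (−1.24, 0.0212), p53 and senescence (−0.56, 0.0175), oxidative phosphorylation (−0.37, 0.0105), imprinted (−0.99, 0.0158) and glycolysis genes (−0.72, 0.0158). In the last list Pdk1 rose by 3.99 ± 0.51. The adjusted p of these 13 lists was 0.525 to 0.729 with an estimated correlation. Thy1 stood at −1.55, Twist1 at −0.06, Cdkn1a at −0.27, Cdkn2a at 0.21 and Mki67 at 0.08 without a call.

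At day 4 limma on TPM called 0 genes (2078 of 17892 with an unadjusted p under 0.05, against 2302 of 22378 in edgeR). In total 679 genes differed between day 4 and day 0 in edgeR, 463 higher and 216 lower, against 1232 with DESeq2 and 33 with all 10 sums. The count was 439 without the b1 and 421 without the b2 set of day 3, and leaving out 1 set at a time gave log2 ranges of Cnn1 −7.31 to −5.54, Dppa5a 13.15 to 16.21, Epcam 5.65 to 13.44, F3 −6.70 to −4.37, Penk 5.09 to 17.96, Pou5f1 8.89 to 10.86, Sox2 6.57 to 7.71, Stra6 5.13 to 7.67, Tagln −6.86 to −4.95, Tdh 12.03 to 18.11 and Trh 13.86 to 15.20.

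At day 5 pluripotency genes reached high levels, 5 factor transcripts were lower than at day 0 and 19 of 30 fibroblast genes were lower. Dppa5a rose to 1334 CPM, a ratio of 275800 (49510 to 10900000) over the 1 count of day 0 (adjusted p = 5.63e-112). Lin28a rose at least 15720-fold, Dppa3 at least 9875-fold, Zfp42 at least 9330-fold and Dppa4 at least 5556-fold. Pou5f1 reached 62.8 CPM (11.10 ± 1.16) and Sox2 46.7 CPM (7.30 ± 0.91). Of 25 pluripotency genes 20 rose, 24 over the list alone (median 11.998, bounded 10.98, camera adjusted p = 7.67e-12). The other largest rises were the germ cell gene Morc1 (at least 5487-fold, no call in DESeq2), the glutathione peroxidase gene Gpx2 (at least 5118-fold) and Sp8 (at least 5067-fold). Among the factors Jdp2 fell by 3.81 ± 0.59 (adjusted p = 1.74e-08) to 26.9 CPM, Map2k6 by 3.08 ± 0.55 to 69 CPM and Esrrb by 2.83 ± 0.51 to 159 CPM. Kdm2b fell by 1.71 ± 0.52 (adjusted p = 0.0262) to 104 CPM and Nanog by 1.54 ± 0.49 (0.0368) to 198 CPM. Sall4 (0.60, 0.635) and Glis1 (−2.64, 0.655) were not called. The median of the factor list was −2.64 (camera adjusted p = 0.000907).

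Of 30 fibroblast genes 19 fell at day 5, 22 over the list alone (median −3.19, camera adjusted p = 1.21e-13), with Col6a1 at −7.94, Loxl1 at −7.54 and Col1a1 at −5.30 ± 0.62, or 30.4 CPM, though a few cells held most of it (−6.93 without the highest cell of each set, −7.03 without cells with few genes). Of 16 contractile genes 12 fell (median −3.85, camera adjusted p = 1.81e-07), with Cnn1 at −12.40 ± 1.18 and Tagln at −6.60. The other largest falls were the collagen gene Col12a1 (−10.12), the stromal gene Cd248 (−9.53), the cyclooxygenase gene Ptgs2 (−8.99, 81% of day 0 in 1 cell), Ccl2 (−8.54 ± 0.77), Bdnf (−7.58) and the integrin gene Itga11 (−7.57). Of 25 epithelial genes 6 rose and 1 fell, or 11 and 2 over the list alone (median 2.88, bounded 2.13, camera adjusted p = 0.000688), with Ap1m2 at least 2869-fold, Elf3 at least 2190-fold and Epcam 9.38 ± 1.18 higher. Cdh1 stood at 1.56 (0.103), but was called without the b1 set of day 0 (2.21, 0.00673), with equal totals per cell (0.0321) and without the highest cell of each set (0.000196). Of 19 S phase genes 6 rose, 7 over the list alone (median 1.13, camera adjusted p = 0.000534), including the replicative helicase genes Mcm5 (2.69 ± 0.51) and Mcm2 (2.18). Of 21 G2/M genes Cenpa rose (1.66), or 3 over the list alone (median 0.83, 0.00238). Of 20 p53 and senescence genes 5 fell, 6 over the list alone (median −0.25, 0.0345), including Fas (−4.51), Btg2 (−2.78) and Ccng1 (−2.40). Of 14 germline genes 3 rose, 7 over the list alone (median 9.13, bounded 5.76, 4.11e-09), among them Hormad1 (at least 124.8-fold). Polycomb genes (median 1.19, 0.0109) included rises of Suz12 (1.79), Jarid2 (1.63) and Mtf2 (1.497), and DNA methylation genes (1.13, 0.0228) of Dnmt3b (2.91) and Tet2 (1.59). BMP response (−1.72, 0.000137), AP-1 (−1.34, 0.00744, with Junb at −3.05), imprinted (−0.87, 0.0228) and oxidative phosphorylation genes (−0.42, 0.0154) had medians below 0, and endothelial genes (1.56, 0.0403) above it. For these 16 lists the adjusted p with an estimated correlation was 0.436 to 0.733. Thy1 (−2.59), Twist1 (−1.87, 0.617), Cdkn1a (−0.99, 0.312, but 0.0458 without the b1 set of day 0), Cdkn2a (0.48) and Mki67 (0.24) were not called.

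At day 5 limma on TPM called 0 genes (2708 of 17892 with an unadjusted p under 0.05, against 3064 of 22378 in edgeR). DESeq2 called 2148 and did not call Nanog (equal totals per cell gave it 0.0735). In total 1059 genes changed in edgeR, 572 higher and 487 lower, against 158 with all 10 sums. Without the b2 set of day 3 the count was 691, and without the b1 or b2 set of day 3 Kdm2b (0.121 and 0.129) and Nanog (0.194 and 0.217) were not called, and leaving out 1 set at a time gave log2 ranges of Ccl2 −9.44 to −5.60, Cd248 −10.01 to −8.80, Cnn1 −13.03 to −11.26, Dppa5a 17.45 to 20.51, Epcam 8.14 to 15.94, Pou5f1 10.16 to 12.13, Ptgs2 −9.52 to −8.17 and Sox2 6.87 to 8.01.

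The comparison of day 7 with day 0 spans the whole course. At day 7, 22 of 25 pluripotency, 12 of 25 epithelial and 10 of 19 S phase genes were higher, and 23 of 30 fibroblast genes were lower. Dppa5a rose to 2563 CPM, a ratio of 530000 (95130 to 20930000, adjusted p = 1.51e-120), in 58 of 65 cells. Dppa3 rose at least 36590-fold, Zfp42 at least 15490-fold and Lin28a at least 11550-fold. Pou5f1 reached 86.1 CPM (11.55 ± 1.18, adjusted p = 5.4e-20) and Sox2 46.3 CPM (7.29 ± 0.91). Of 25 pluripotency genes 22 rose, 23 over the list alone (median 12.91, bounded 11.96, camera adjusted p = 1.29e-11). The other largest rises were the X-linked genes Rhox6 (at least 8776-fold, 59% in 1 cell) and Trap1a (at least 7964-fold), and the embryonic globin genes Hbb-bh1 (ENSMUSG00000052217, at least 33870-fold, 59% in 1 cell) and Hba-x (at least 28750-fold, 56% in 1 cell), which had counts in 7 and 8 of 65 cells. Of 25 epithelial genes 12 rose, 17 over the list alone (median 3.66, camera adjusted p = 8.55e-08). Cdh1 rose by 3.27 ± 0.58 (adjusted p = 1.42e-06) from 27.8 ± 14.2 to 267 CPM, Epcam by 10.05 ± 1.21, and Elf3 at least 7821-fold. Of 30 fibroblast genes 23 fell, 24 over the list alone (median −3.77, camera adjusted p = 9.89e-15), including S100a4 (at least 3564-fold), Lox (−9.36), Thy1 (−8.04 ± 2.21) and Col1a1 (−4.85 ± 0.61, 41.3 CPM, 53% of it in 1 cell). Of 16 contractile genes 13 fell (median −3.58, 1.89e-06), including Tagln (−6.13), Myl9 (−5.99) and Acta2 (−5.18). The largest falls were those of the caveolin gene Cav1 (at least 9689-fold), Itga11 (at least 6521-fold), Gpr176 (at least 5494-fold), Lrrc32 (ratio 33530, 6017 to 1324000), Msmp (ratio 33090, 9160 to 273200, 76% of day 0 in 1 cell), Clcf1 (ratio 15810, 2838 to 624700, 54% in 1 cell), Col12a1 (−12.25) and Plau (−11.89).

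The factors went different ways by day 7. Jdp2 fell by 6.30 ± 0.68 (adjusted p = 4.89e-18) to 4.76 CPM, Map2k6 by 3.31 ± 0.56, Esrrb by 3.06 ± 0.52 and Kdm2b by 1.72 ± 0.52 (0.0198). Nanog was at 366 CPM (−0.65, 0.547), Glis1 at −4.72 (0.246) and Sall4 at 1550 CPM (1.21, 0.064), and DESeq2 called both of the latter (Glis1 0.00162, Sall4 0.047). Sall4 was also called with RLE scaling (0.0284), with equal totals per cell (0.0401), without the highest cell of each set (0.0116) and without the b2 set of day 0 (0.0197). The factor list had a median of −3.06, with 4 falls, or 5 and 1 rise over the list alone (camera adjusted p = 0.00285). Of 19 S phase genes 10 rose, 14 over the list alone (median 1.56, 9.91e-05), with Mcm5 (2.95 ± 0.51) and the licensing factor gene Cdc6 (2.79) as the largest. Of 21 G2/M genes 2 rose, Bub1 (2.39) and Cenpf (1.98), or 8 over the list alone (median 1.01, 0.000157). Of 6 DNA methylation genes 3 rose, Dnmt3b (2.55), Tet2 (2.50) and Uhrf1 (1.45) (median 1.27, 0.0188). Of 11 Polycomb genes 4 rose, 6 over the list alone (median 1.37, 0.0128). Of 14 germline genes 5 rose, 8 over the list alone (median 9.58, bounded 6.23, 8.55e-08), including Stk31 (at least 1161-fold) and Hormad1 (at least 1128-fold). Of 9 2-cell-like genes 4 rose, 7 over the list alone (median 11.53, bounded 7.51, 6.47e-09), but the list result rests on 1 cell, which held all counts of Zscan4c (ENSMUSG00000054272) and 93.81% or more of the summed TPM of Zscan4b, Zscan4f, Tcstv1, Duxf3, Gm8300 and Usp17lc in the set. Of 10 endothelial genes 2 rose, 4 over the list alone (median 2.78, 0.0308). Of 11 AP-1 genes 3 fell, Fosl1, Junb and Fos (median −1.34, 0.0024). Of 7 BMP response genes Bmp4 (−2.41) and Id3 (−1.64) fell, 4 over the list alone (median −1.64, 0.000338). Of 20 p53 and senescence genes 3 fell (median −0.61, 0.0338), and of 22 oxidative phosphorylation genes none was called (−0.49, 0.0256). With an estimated correlation the adjusted p of these 16 lists was 0.359 to 0.628. No camera call was made for interferon response (median −2.06, adjusted p = 0.0742), glycolysis (0.53, 0.112), cholesterol synthesis (0.74, 0.112), extraembryonic endoderm (3.31, 0.274), trophoblast (1.51, 0.209), neural (2.96, 0.132), macrophage (1.05, 0.328), keratinocyte (0.43, 0.314), imprinted (−1.15, 0.0626), sex chromosome (−0.25, 0.905) or skeletal muscle genes (−0.91 against a mean of 0.49, 0.918), although the muscle gene Mylpf rose by 6.61 ± 0.69. Twist1 (−1.88, 0.535), Cdkn1a (−1.14, 0.16, but 0.0159 without the b1 set of day 0), Cdkn2a (0.60) and Mki67 (0.86, 0.436) were not called.

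In total 1477 genes changed at day 7, 794 higher and 683 lower, against 2875 with DESeq2, 352 with all 10 sums and 582 with limma on TPM. Of the limma calls 88.7% were higher, against 53.8% in edgeR, 47.6% in DESeq2 and 45.5% with all 10 sums. Limma and edgeR shared 228 calls in the same direction. The count was 941 without the b1 and 918 without the b2 set of day 3, and leaving out either ended the call of Kdm2b (0.0906 and 0.0948), as leaving out the b2 set of day 0 (0.052) or of day 3 (0.117) did for Thy1, and leaving out 1 set at a time gave log2 ranges of Cdh1 2.82 to 3.92, Dppa5a 18.40 to 21.45, Epcam 8.82 to 16.61, Pou5f1 10.62 to 12.58, Sox2 6.86 to 8.00 and Thy1 −8.85 to −6.03.

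**Figure D2:**
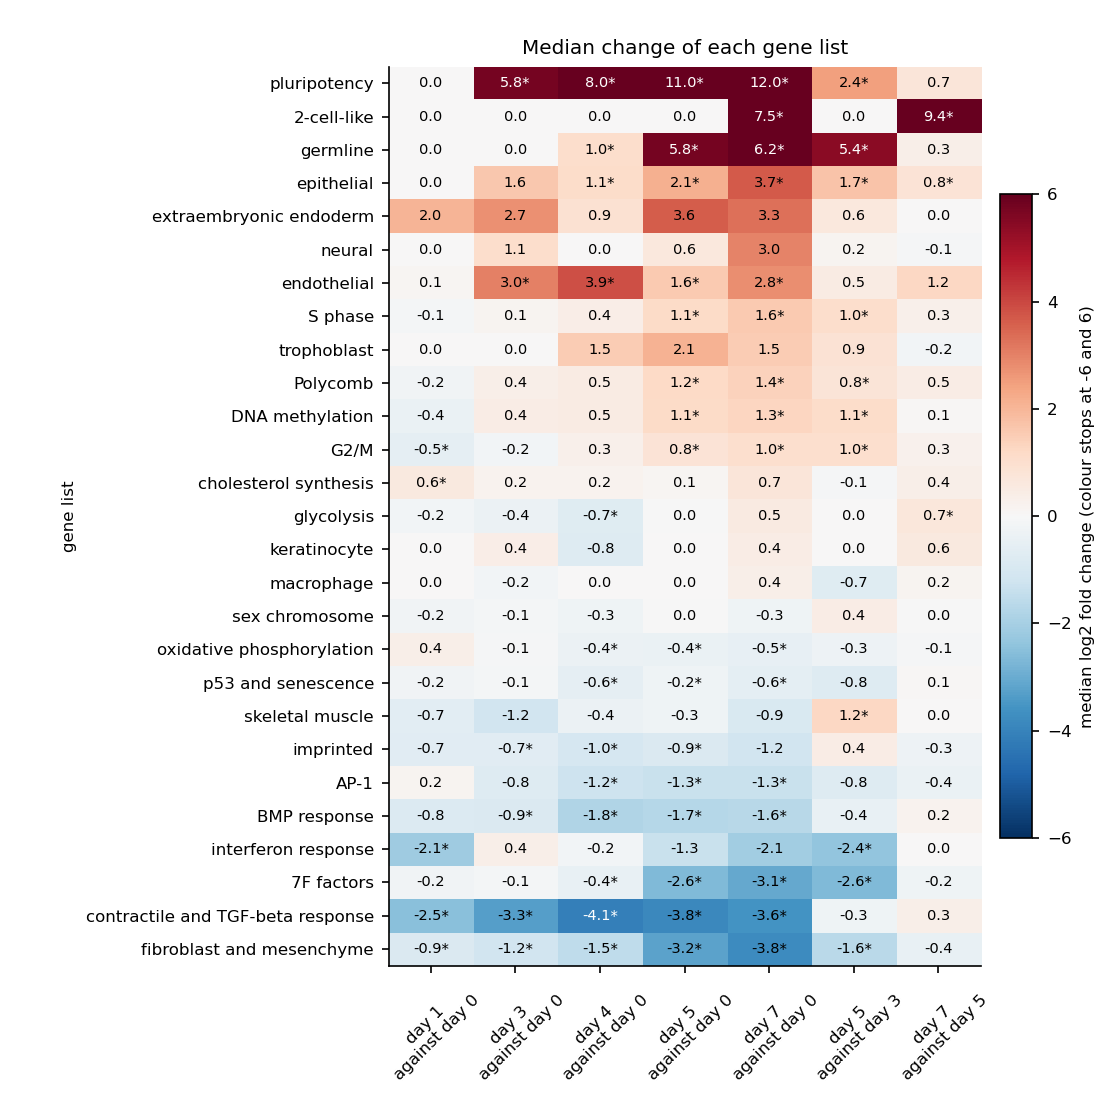
Median log2 fold change of 27 gene lists in 7 comparisons, with bounds for genes without counts and an asterisk for a camera adjusted p under 0.05 at the preset correlation. The pluripotency median rose from 0 at day 1 to 11.96 at day 7, and the fibroblast median went from −0.9 to −3.8.

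The step from day 3 to day 5 shows which genes moved after the early fall of contractile genes. Of 25 pluripotency genes 15 were higher, Dppa3, Dppa4 and Dppa5a among them, and 4 factor transcripts were lower, while 3 of 19 S phase and 3 of 14 germline genes were called higher. Dppa5a rose by 6.02 ± 0.48 (adjusted p = 1.44e-31), from 20.6 ± 28.2 to 1334 CPM, and Lin28a by 8.19 ± 0.73, from 0.778 ± 0.050 to 228 CPM. The other largest rises were Trap1a (9.69), Sp8 (6.65), Morc1 (6.52), Dppa3 (6.12 ± 0.60), Dppa4 (5.95) and the X-linked homeobox gene Rhox5 (5.82). Zfp42 rose by 3.86 ± 0.65 (0.0724 without the highest cell of each set), while Pou5f1 (2.40, adjusted p = 0.15) was not called. Over the pluripotency list alone 19 genes rose (median 2.45, camera adjusted p = 5.47e-08). Jdp2 fell by 3.69 ± 0.58 (adjusted p = 1.53e-07), from 348 ± 143 to 26.9 CPM, Esrrb by 2.83 ± 0.51 from 1134 ± 397 CPM, Map2k6 by 2.63 ± 0.54 from 428 ± 17.4 CPM and Nanog by 1.73 ± 0.49 (0.0289) from 659 ± 286 CPM. The factor list had a median of −2.63 (camera adjusted p = 0.00398), with Kdm2b (−1.35, 0.24), Sall4 (0.96, 0.456) and Glis1 (−3.05, 0.807) not called. Of 30 fibroblast genes 9 fell, and over the list alone 13 fell and 1 rose (median −1.61, 5.04e-06), with Loxl1 at −5.57. Col1a1 stood at −1.56 (0.0838), and was called without the b1 (0.0121) or b2 (0.0101) set of day 0, with RLE scaling (0.0488), and without cells with few genes (−3.29, 1.08e-06). The other largest falls were Col6a3 (−6.77 ± 0.87), Fxyd2 (−6.73), Acy3 (−5.26, 60% in 1 cell), Psca (−5.22), Tnfsf9 (−5.06), Tnfaip2 (−4.76) and Prkcb (−4.70, 58% in 1 cell).

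Contractile genes went both ways from day 3 to day 5 (camera adjusted p = 0.848). Acta2 rose by 2.53 ± 0.44 and Ankrd1 by 2.22, and Cnn1 fell by 5.15. Besides the pluripotency list, 7 lists with a median above 0 passed camera. They were S phase (1.03, 1.01e-05, 3 of 19 called or 6 over the list alone, with Mcm5 at 1.97 and Mcm3 at 1.92), G2/M (1.01, 3.76e-06, 1 of 21 or 2, Bub1 at 2.12) and germline genes (5.82, 6.89e-09, 3 of 14 or 6, with Dazl at least 909.8-fold). They were also DNA methylation (1.09, 0.0281, 1 of 6 or 3, Uhrf1 at 1.88), Polycomb (0.75, 0.0206, 1 of 11, Ezh2 at 1.73), epithelial (1.71, 0.00644, 4 rises and 1 fall, with Ap1m2 at 7.31 and Elf3 at 4.83) and skeletal muscle genes (1.28, 0.0278, 1 call, Mylpf at 3.75). The interferon response median was −2.36 (0.0278), with 2 falls or 3 over the list alone. An estimated correlation gave these 11 lists an adjusted p of 0.578 to 0.739. Epcam (2.24, 0.332), Cdh1 (1.35, 0.373), Thy1 (−2.76), Twist1 (−1.86), Cdkn1a (−1.36, 0.175), Cdkn2a (0.21), Sox2 (0.30) and Mki67 (0.28) were not called.

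From day 3 to day 5 limma on TPM called 0 genes (1990 of 17892 with an unadjusted p under 0.05, against 1846 of 22378 in edgeR). DESeq2 called 998 (23.4% higher) and did not call Morc1, Dppa3, Dppa5a, Zfp42 or Nanog. In total 383 genes changed in edgeR, 144 (37.6%) higher and 239 lower, against 12 with all 10 sums. Lower genes outnumbered higher ones without the b1 set of day 3, but not without its b2 set. The count was 680 or 690 without the b1 or b2 set of day 0 (Pou5f1 0.021 and 0.0207, Kdm2b 0.0489 and 0.0486, Cdkn1a 0.0188 and 0.0205), 161 without the b1 set of day 3 (Esrrb 0.0547, Zfp42 0.0983, Nanog −1.20 with p = 1) and 217 without the b2 set of day 3 (Nanog 0.14, Pou5f1 0.000441, Epcam 0.0131), and leaving out 1 set at a time gave log2 ranges of Acy3 −5.96 to −3.85, Col6a3 −7.19 to −6.18, Dppa3 5.12 to 12.26, Dppa4 5.26 to 7.31, Dppa5a 5.04 to 10.95, Fxyd2 −7.16 to −6.13, Morc1 5.51 to 16.48, Psca −5.75 to −4.39, Rhox5 5.34 to 6.56, Sp8 6.08 to 7.60, Tnfsf9 −5.50 to −4.44, Trap1a 8.90 to 12.03 and Zfp42 2.87 to 10.47.

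Several of the largest rises from day 5 to day 7 came from 1 or a few cells. Hbb-bh1 rose at least 30570-fold and Hba-x at least 25950-fold, with the globin genes Hba-a1 (ratio 43100, 11930 to 355900) and Hba-a2 (10.54 ± 1.36). Zscan4c rose at least 3487-fold in 1 cell. The blood and endothelial factor gene Gata2 rose by 4.28 ± 1.04 (adjusted p = 0.0104), the mitophagy gene Bnip3 by 3.56 ± 0.87 (0.0124), from 16.8 to 199 CPM in 52 of 65 cells, and Car4 by 3.24 (87% in 1 cell). Spry4, a feedback inhibitor of FGF signalling, fell by 4.36 ± 0.67 (7.62e-08) from 172 to 8.36 CPM, Pdk1 by 3.35 ± 0.65 from 176 to 17.3 CPM, Trh by 3.77 ± 0.67 and Crym by 6.70 ± 0.95 (59% in 1 cell). The other largest falls were Grem1 (−7.30, 99.98% in 1 cell), Car3 (−6.26, 60% in 1 cell), Asb4 (−4.42) and the mesendoderm gene Mixl1 (−4.20, 79% in 1 cell). Jdp2 fell by 2.50 ± 0.58 (0.00608). Of 25 epithelial genes the keratin gene Krt18 rose (3.18 ± 0.73), or 2 over the list alone (median 0.82, camera adjusted p = 0.0129). The glycolysis median was 0.67 (0.0353), although its called member Pdk1 fell, and the 2-cell-like median was 11.53, bounded 9.40 (2.01e-13), with 1 call or 4 over the list alone, and it rests on the same 1 cell as at day 7 against day 0, which held 93.81% or more of the summed TPM of 7 of its genes. With an estimated correlation the adjusted p of these 3 lists was 0.418 to 0.961. No pluripotency gene was called (median 0.73, 0.693), and 4 of 30 fibroblast genes fell (−0.45, 0.187). Cdh1 stood at 1.71 (0.724) and Thy1 at −5.45 (0.465). The factors other than Jdp2 differed by −2.08 (Glis1) to 0.88 (Nanog) without a call, as did Pou5f1 (0.45), Sox2 (−0.01), Zfp42 (0.73), Dppa5a (0.94), Epcam (0.67), Col1a1 (0.44, but 2.17 and 0.0208 without cells with few genes), Twist1 (−0.01), Cdkn1a (−0.15), Cdkn2a (0.12) and Mki67 (0.62).

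From day 5 to day 7 limma on TPM called 0 genes (1350 of 17892 with an unadjusted p under 0.05, against 940 of 22378 in edgeR). DESeq2 called 474 (36.3% higher) and did not call Gata2, Car4, Car3, Asb4, Mixl1 or Trh. In total 124 genes changed in edgeR, 23 (18.5%) higher and 101 lower, against 18 with all 10 sums. The count was 220 or 221 without the b1 or b2 set of day 0 and 69 without either set of day 3, which ended the calls of Jdp2 (0.076 and 0.083), of Asb4 without b1 (0.0534), and of Gata2 (0.0959) and Car3 (0.0533) without b2. Without each gene's highest cell in each set it was 62, with Gata2 (0.244), Bnip3 (0.0582), Asb4 (0.268), Trh (0.46), Car4, Grem1, Car3 and Mixl1 (each 1) not called.

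The shares of cells with a detected gene show how evenly these genes were spread. Dppa5a was detected in 0 of 20 and 0 of 54 cells of the day 0 sets, which allow shares of up to 15% and 5.56%. It was found in 10.3% of cells at day 1, 6.56% (b1) and 41.4% (b2, 28.6 to 55.1) at day 3, 45.8% at day 4, 74.7% (63.6 to 83.8) at day 5 and 87.7% (77.2 to 94.5) at day 7. Sox2 was in 5.56% of b2 cells at day 0 (1.16 to 15.4) 94.8% at day 1 (85.6 to 98.9) and 55.7% (b1) and 93.1% (b2) at day 3, ahead of Pou5f1, which was in 20.7% at day 1, 9.84% (b1) and 46.6% (b2) at day 3 and 78.5% at day 7 (66.5 to 87.7). Zfp42 came later, in 0 of 58 cells at day 1 (up to 5.17%), 4.92% of b1 and 31.03% of b2 cells at day 3 and 75.4% at day 7. Cdh1 went from 18.5% of b2 cells at day 0 to 83.1% at day 7 (71.7 to 91.2), and Col1a1 from 98.1% to 15.4% (7.63 to 26.5). Jdp2 was in all b2 cells up to day 3, in 40.5% at day 5 (29.6 to 52.1) and in 23.1% at day 7 (13.5 to 35.2). Map2k6 was in 15.3% of cells at day 4 (7.22 to 26.99), against 96.7% or more at day 3 and 53.2% at day 5 (41.6 to 64.5). At TPM of 10 or more the shares of b2 cells were 46.6% for Sox2, 8.62% for Pou5f1 and 1.72% for Dppa5a at day 1 (3.45% for Dppa5a on thinned counts), 9.26% for Cdh1 at day 0, and 9.23% for both Col1a1 and Jdp2 at day 7. For Dppa5a in b2 at day 5 the share was 51.9% at TPM of 10 or more and 60.8% on thinned counts. Both lie below the interval given above for that day.

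**Figure D3:**
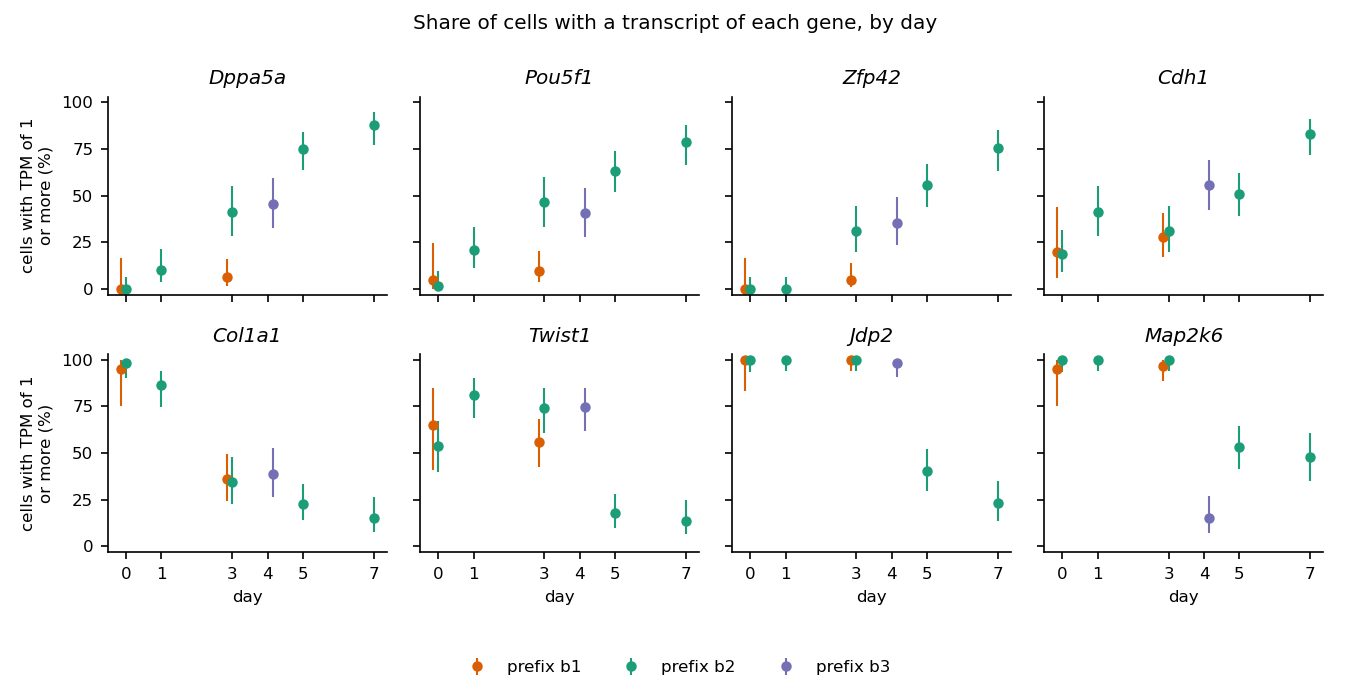
Percent of cells with TPM of 1 or more against day, with 1 point per set of 10 or more cells and exact 95% intervals. Dppa5a went from 0 to 87.7% of b2 cells, and Col1a1 from 98.1% to 15.4%.

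Scores per cell show that cells of 1 day differed widely. The median pluripotency score of b2 cells was 0.243 at day 0, 0.522 at day 1, 0.873 (quartiles 0.514 to 1.31) at day 3, 1.38 (0.802 to 5.53) at day 5 and 4.91 (2.94 to 5.84) at day 7. The median fibroblast score of the same sets was 3.45, 2.79, 2.16, 0.979 and 0.848. Across the cells of a set, Spearman's rho between both scores was 0.3338 in b1 and −0.05 in b2 at day 0, −0.0226 at day 1, −0.2947 in b1 and −0.5454 in b2 at day 3, −0.3033 at day 4, −0.6779 at day 5 and −0.4214 at day 7. The rho between pluripotency and epithelial scores was 0.3644 in b1 and 0.2967 in b2 at day 3, 0.4129 at day 4, 0.7007 at day 5 and 0.2874 at day 7. These values describe cells within 1 set, and cells are not independent replicates, so no p is given.

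**Figure D4:**
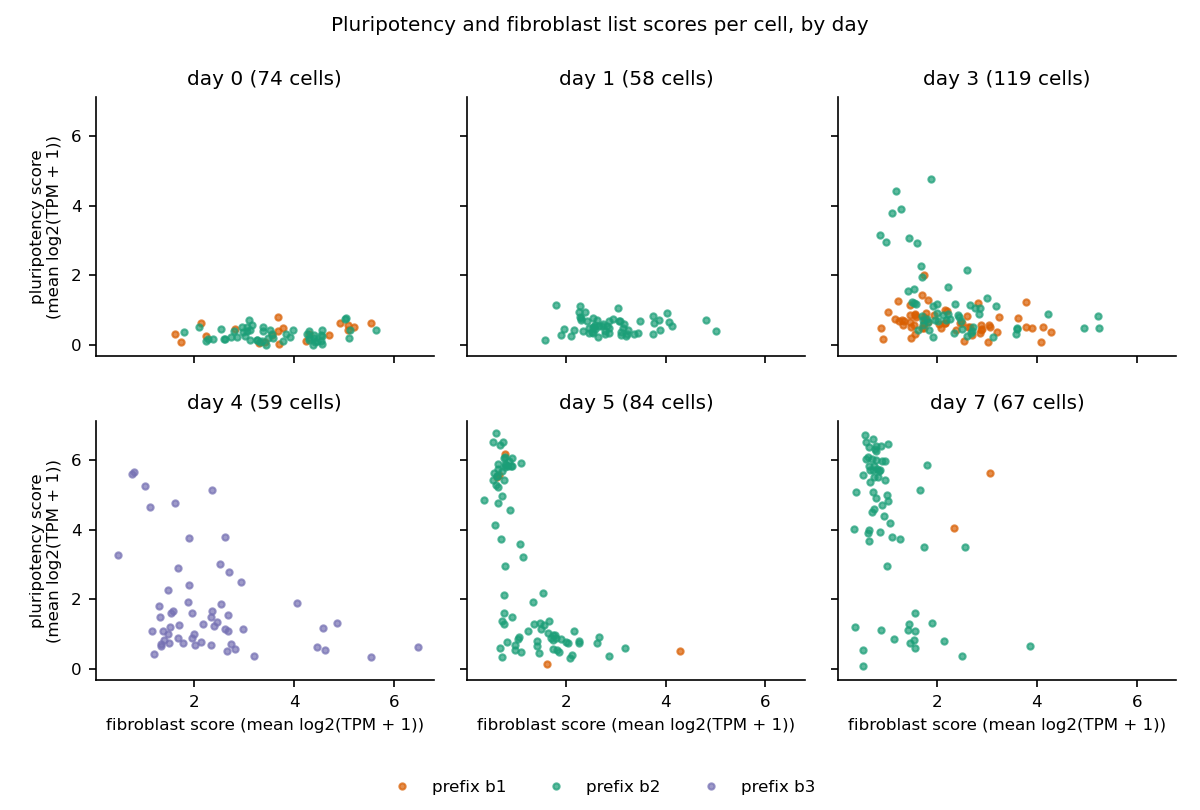
Pluripotency score against fibroblast score of each cell (both mean log2(TPM + 1) of the list), with 1 panel per day, 1 point per cell and colour by prefix. At day 5 the quartiles of the pluripotency score of b2 cells were 0.802 and 5.53.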

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

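The tests of the 3 patterns weighed here were chosen after the results were seen, as were Gata1, Klf1 and Alas2 and the cells singled out.

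Transcripts of Sall4, Esrrb, Nanog, Map2k6, Jdp2 and Kdm2b stood at 339 to 1129 CPM at day 0, although Nanog, Esrrb and Sall4 are known as genes of pluripotent cells. RNA from pluripotent cells in these libraries would bring its abundant genes along, but 2 of 19 abundant pluripotency genes (Klf4 and Tbx3) reached 10% of the level needed, and Dppa5a was at 0.0033 CPM where 4023.7 CPM would be needed. An active native network was also excluded, since 2 of 25 pluripotency genes (the same pair) had 10 CPM or more in both day 0 sets. Cells of day 1 with a day 0 label were excluded, since 5.556% of b2 cells of day 0 had Sox2 (upper bound 15.389%) against a lower bound of 85.62% at day 1. Transcripts from vectors delivered before day 0 stay open as the remaining explanation, untested, since gene counts do not separate vector from native transcripts.

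Map2k6 transcripts were nearly absent in the day 4 set and present on the days before and after it. Lower depth is not the cause, since at 300000 counts in every cell 10.169% of day 4 cells had the gene (3.824 to 20.832) against 50.633% at day 5 (39.141 to 62.076). A general fall of the factors by day 4 is excluded too, with 0 of 6 other factors below 10% of their day 3 mean. A property of the cells of prefix b3, such as a lost or different vector, cannot be told apart from day 4, because 1 day has a set of this prefix. A change with time that reverses by day 5 stays open for the same reason.

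Hbb-bh1 was concentrated in 2 cells of prefix b2 at day 7 (TPM 40456 and 40911), together with Gata1 (265 and 445), Klf1 (57.5 and 95.6) and Alas2 (1152 and 684), regulators and an enzyme of red cell formation. Free globin RNA in the set is excluded, since 5 of the other 63 cells had Hbb-bh1 at TPM of 1 or more and 1 at 10 or more (71.9). A blood cell captured together with a cell of the culture stays open. Of the 2 cells 0 reached the lower quartile of the set in the pluripotency (2.9425) or fibroblast score (0.6666). However, 1 of the other 63 cells also lay below both. The first of the 2 cells also held Pou5f1 (52.49, against a median of 71.94 in the set) and the second did not. Neither held Dppa5a or Cdh1. The 2 cells also held factor transcripts, Nanog (79.2 and 69.2) and Map2k6 (1144 and 891). That Map2k6 level lay far above the upper quartile of b2 cells at day 7 (24.31). It lay within the quartiles of b2 cells at day 0 (169.405 to 1204.637). Blood cells carried over with the embryonic fibroblasts stay open. The share of 3.077% of day 7 cells (0.375 to 10.677) lies under the 4.054% that 0 of 74 day 0 cells allows. In addition, 1 cell of day 1 (b2) and 1 of day 3 (b1) held Hba-a1 (1049 and 1206) and Hba-a2 (517 and 704). Both lacked Hbb-bh1, Gata1, Klf1 and Alas2. Their fibroblast scores were 2.9509 and 3.2515, and they held Map2k6 (1042 and 1419) and Nanog (419 and 730), so they are not read as blood cells. A biological explanation, the formation of blood-like cells in the culture, may apply but was not tested, and 1 other day 7 cell held Hba-x (11956) without Hbb-bh1, Gata1, Klf1 or Alas2.

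The other results are given as values. Some named genes moved in opposite directions from day 0 to day 3 in prefixes b1 and b2, by more than 1 log2 unit in each and with 10 CPM or more in both prefixes, and the difference was not tested. They were 6 of 174 named genes, and 240 of 9049 genes at this level did so. The log2 change in b1 and then b2 was 8.762 and −1.643 for Car4, 1.761 and −1.13 for Col6a1, −1.28 and 1.482 for the BMP target Id4, 6.279 and −2.637 for the interferon-induced gene Ifit1, −1.69 and 4.329 for the neural tubulin gene Tubb3, and −1.086 and 1.139 for Xist. Of the summed TPM 1 cell held 53.8% for Ifit1 and 42.5% for Tubb3.

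The 7 cells of prefix b1 at days 5 and 7, too few for the comparisons, carried pluripotency genes above the day 0 level. Dppa5a was found in 6 of 7 (85.7%, 42.1 to 99.6) against 0 of 74 at day 0, Pou5f1 in 5 (71.4%, 29.04 to 96.33) against 2, Zfp42 in 5 against 0 and Cdh1 in 6 against 14. Jdp2 was found in 3 of the 7 cells. Fibroblast genes were found too, with Col1a1 in 1 of 5 cells at day 5 and 2 of 2 at day 7, Prrx1 in 2 of 5 and 2 of 2 and Twist1 in 1 of 5 and 2 of 2, where 15.4% of b2 cells at day 7 had Col1a1.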

How the results depend on the processing

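Leaving out each gene's highest cell in each set, or the day 4 set, was chosen after seeing the data. For the comparisons 1, 3, 4, 5 and 7 against 0, 5 against 3 and 7 against 5, edgeR called 265, 703, 679, 1059, 1477, 383 and 124 genes. No alternative reversed a call among 238 results of named genes, which leave out genes named only as members of a list. DESeq2 called 723, 1549, 1232, 2148, 2875, 998 and 474, and limma on TPM 0, 0, 0, 0, 582, 0 and 0. Limma tested 17892 genes, fewer than edgeR, and 1316, 2051, 2078, 2708, 3415, 1990 and 1350 had an unadjusted p under 0.05. Taking all 10 sums, which adds the sets of 5 and 2 cells, left 1, 37, 33, 158, 352, 12 and 18 genes. The deviations of the sets of prefixes b1 and b2 from their day means correlated at 0.0574 over the 2 pairs, so the prefixes were not shown to pair the sets. With the replicate block 6, 191, 290, 432, 23 and 16 genes were called, without a value for day 4, and 42.76% of those of day 5 and 40.97% of those of day 7 against 0 were higher, against 54.01% and 53.76%. Leaving out each set of days 0 and 3 in turn gave 145 to 440, 261 to 793, 421 to 846, 691 to 1271, 918 to 1678, 161 to 690 and 69 to 221 genes, with a lone set of a day assumed to vary like the others. Without each gene's highest cell 62 genes were called in 7 against 5. RLE scaling, no filter, equal totals per cell, leaving out 5 cells with few genes (over 3 MAD below the median of their set in log number of genes) and leaving out the day 4 set kept each count within 1.5 times. Without a filter 25691 genes were tested. The cause of these differences was not tested. The median log2 fold change of all genes was 0.1136 for 3 against 0 and −0.1405 for 5 against 3, and limma on TPM put it at 0.2548 for 3 and 0.2068 for 4 against 0.

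Of 27 lists 5, 6, 13, 16, 16, 11 and 3 passed camera in the same order. An estimated correlation left 0, 0, 0, 0, 0, 0 and 0 of them, and fry, which tests whether the genes of a list move 1 way on balance, called 0, 2, 0, 1, 9, 1 and 1. The replicate block gave 6, 7, 18, 17, 10 and 3. Named genes gave 238 results with 3265 alternatives, of which 2901 had the same outcome, 336 lost a call, 28 gained one and 0 reversed. Another 95 values changed sign with neither past the threshold. Results of genes named only as members of a list, such as Ankrd1, were not among these. Lost calls came mostly from limma on TPM (139), all 10 sums (85), the replicate block (51) and DESeq2 (21). Of 152 called results of named genes, 70 moved by over 1.5-fold when 1 set of day 0 or 3 was left out. Those of day 7 against day 5 are among the 152 but could hardly move, as no set of these days was left out.

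In single cells, Map2k6 was found in 15.254% of day 4 cells and 47.692% of b2 cells at day 7 at TPM of 1 or more, and in 6.78% and 30.769% at TPM of 10 or more. The median pluripotency score of b2 cells differed by 4.6687 between days 7 and 0, by 6.9805 with a pseudocount of 0.1 and by 4.8965 on thinned counts. For the fibroblast score these values were −2.6032, −4.1960 and −3.2905, and for the epithelial score 1.1958, 2.0692 and 1.3194, or 1.2456 with members found in 10 or more cells. Of 220 shares 67 moved at TPM of 10 or more and 14 on thinned counts. None of the 12 differences of pluripotency, fibroblast and epithelial scores from day 0 in b2 changed direction. Their size was less stable. It moved by more than the SD between sets in 11 with a pseudocount of 0.1 and in 8 on thinned counts. With members found in 10 or more cells 1 moved. Scores of other lists were not included in these counts. The day 4 set had the lowest median depth, 0.983 M counts per cell, and the self-test recovered 14.8% of 4-fold changes at day 7.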

Other observations

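The test of the factor fall, the clusters described and the cells singled out were chosen after the results were seen, while the marker lists were not.

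Cell cycle genes were spread differently over cells late in the course. The median S phase score was 4.31 in b1 and 2.78 in b2 at day 0, 5.66 at day 4, and in b2 5.85 at day 5 and 6.04 at day 7. The median G2/M score was 2.13 and 1.36 at day 0, 5.18 at day 4, 5.84 and 5.78. S phase and G2/M scores varied together across cells at day 0 (Spearman's rho 0.76 in b1 and 0.74 in b2) and at day 4 (0.55), and not at day 5 (0.05) or day 7 (−0.05). Scores per cell depend on depth, and no cycling rate is read from them. In the same sets the transcripts of Nanog and Sall4 tracked the pluripotency score across cells at days 5 and 7. For Nanog rho was −0.02 in b2 at day 3, 0.54 at day 5 and 0.72 at day 7, for Sall4 it was 0.60 at day 4, 0.65 and 0.63, and for Esrrb 0.15 at day 5 and 0.58 at day 7 (0.38 and 0.68 on thinned counts).

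Clustering of all cells gave 6 clusters, of which cluster 4 (80 cells) expressed 21 fibroblast markers above the other cells, cluster 5 (74 cells) all 25 pluripotency markers and cluster 6 (17 cells) 18 pluripotency and 13 epithelial markers. Clusters 1, 2 and 3 (99, 98 and 93 cells) were not named, as each expressed at most 4 markers of any list above the other cells. Clusters 2 and 3 went partly with the title prefix. Of the day 3 cells, 43 of 61 of b1 were in cluster 3 and 35 of 58 of b2 in cluster 2. Cluster 5 was led by Fgf4, Pla2g1b and Mcf2, and cluster 6 by the X-linked homeobox gene Rhox9, Gstm3 and Dppa3. In cluster 5 the median TPM of Jdp2 was 0 in b2 at days 5 and 7, while Nanog was at 218 and 381 and Sall4 at 743 and 857. No doublet caller was run, and sizes of clusters are not compared between days. In 1 cell of prefix b2 at day 7 the 2-cell-stage genes Zscan4c (TPM 2596), Zscan4f (1160), Tcstv1 (393) and Duxf3 (779) stood beside Dppa5a (11041) and Pou5f1 (12.4). Another cell of that set held Hba-x (11956), Hba-a1 (17967) and Hba-a2 (9328) with Dppa5a at 7081 and no Hbb-bh1 or Gata1.

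The fall of Jdp2, Map2k6, Esrrb and Nanog transcripts from day 3 to day 5 could have been a fall in pluripotent-like cells alone, as silencing of vectors on entry into pluripotency would give. This was excluded for Jdp2, Esrrb and Nanog, because in cluster 2, whose cells had few pluripotency transcripts (median Dppa5a TPM of 1.35 in b2 at day 5), 3 of 4 factors had a day 5 upper quartile below the day 3 lower quartile. For Map2k6 the quartiles leave it open, as its day 5 upper quartile (135.19) lay above the day 3 lower quartile (96.62). Its median TPM in b2 cells of cluster 2 was nevertheless lower, 186.89 at day 3 and 19.08 at day 5. It was detected in 35 of 35 of these cells at day 3 and in 29 of 44 at day 5. For Jdp2 the median TPM of b2 cells in cluster 2 went from 245.6 (quartiles 56.7 to 404.7) to 0.93 (0 to 34.2). Whether dilution of vectors, their silencing or cells without vectors account for it was not tested.

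At TPM of 1 or more 108 of 461 cells had Xist and at least 2 of 4 Y-linked genes, and 11 (2.386%) at TPM of 10 or more, where 231 cells had the Y-linked genes and 87 had Xist.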
